A study of Bos taurus with 10 samples.

How the data were processed

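Longissimus muscle, the long muscle along the back, was sampled from 10 steers of an Angus and Simmental cross at 385 ± 5 days of age. The dams of 5 steers had been fed dried distillers grains and solubles (DDGS) while they were lactating, and the dams of the other 5 had received the control diet that the labels call SBM. Per the labels' protocols, the muscle was ground under liquid nitrogen, total RNA was extracted with a column kit, and libraries were made with the TruSeq Stranded Total RNA kit. This kit marks the strand and adds no molecular identifiers. Each library came from 1 animal, and no label gives a sire, a sampling day or a sequencing batch.

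The deposited values are whole-number read counts per gene for 16963 Ensembl cattle gene identifiers, 1 column per animal, which the authors did not scale to a common total. The submitters' processing notes name FastQC 0.10.1, Bowtie2, TopHat2 2.0.9 and HTSeq 0.5.3p7 with the UMD3.1 assembly. The annotation release, the strand setting of the counting, the treatment of duplicate reads and any filter are not given in the sources used here. Reads of near-identical or overlapping genes are therefore uncertain. The table holds no 0 among its 169630 values and its lowest value is 1. Values of 1 made up 21.8% of the table. In 170 rows every library stood at 1, and the highest value was 2 in 149 further rows and 3 in 138. This run of rows could be left if genes without any read were removed and the remaining zeros replaced by 1. No source states that step, and other origins of the values of 1 were not excluded. A value of 1 is called "listed at 1" here and was not read as 1 observed fragment. Every row named a gene identifier, and no per-sample column was left unused.

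Depth was between 16942156 and 24936741 counts per library. For a gene without reads, up to 3 counts cannot be excluded, which is 0.120 to 0.177 CPM (counts relative to the library total) in these libraries. Such limits cover counting error only, since amplified reads are not independent molecules. The spread of each library around the other 9, at mean counts of 100 to 300, was 9.85 to 46.7 times the variance of counting alone. In the 45 pairs of libraries the spread was at least 9.81 times that of counting, and 0 pairs held identical values, so no pair showed the agreement of a repeated deposit of 1 library. That the replicates are separate animals rests on the labels.

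Gene names could not be attached. The reference gene table used here (ARS-UCD2.0 assembly) lists no Ensembl identifiers. That 0 of the 16963 identifiers matched it was therefore fixed beforehand and says nothing about the identifiers themselves. The file pairs no identifier with a name. The 37 lists of gene symbols fixed before the data were examined (fibre types, fat, matrix, metabolism, imprinting and other cell types), their tests and their scores per library were therefore not run. Genes are given by identifier, without coordinates. The rule for named genes, also fixed before the data were examined, allowed at most 2 identifiers per direction for rows without a symbol. These were the genes with the smallest p among those with a mean of at least 1 CPM.

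The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts of all 10 libraries, with TMM normalization, edgeR's default expression filter, robust dispersion estimates, group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are DDGS over SBM. Standard errors were derived from the fitted coefficient and its F statistic, and 95% intervals from them, without adjustment for the number of genes. CPM values of single genes use TMM library sizes. CPM sums over sets of genes use total counts. The separation of the libraries was the median correlation distance between libraries of different groups minus that within groups, over the 500 genes with the most variable log2 CPM (prior count 2), with an exact one-sided permutation test over all splits into the same group sizes. Differences between groups in a single value were tested with exact two-sided permutation tests over 252 assignments, for which the smallest possible p is 0.00794.

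Alternatives fixed before the data were examined were RLE and upper quartile factors, no filter and a stricter filter, the replicate number as a block, each library left out, limma voom with sample weights (limma 3.58.1), DESeq2 1.42.0, edgeR's likelihood ratio and exact tests, non-robust estimates, a threshold of 0.10 and 1 surrogate variable (sva 3.50.0). Sets of genes that vary together were sought after the data had been seen. Genes with at least 100 counts in some library and a standard deviation above 1 on the log2(CPM + 1) scale were clustered by average linkage on correlation distance, with a distance limit of 0.2 and a minimum of 10 genes. The fits were tested on simulated counts with the means, library sizes and dispersions of these libraries and 200 changed genes. Only genes that passed edgeR's filter were simulated, each drawn independently. The simulated counts thus held no sets of genes varying together, and zeros were not replaced by 1. Shares of recovered and false calls may differ in the real libraries. In that simulation of DDGS against SBM, edgeR's quasi-likelihood test ran on 11913 genes and called 17% of the 100 genes with a 2-fold change and 55% of the 100 with a 4-fold change. Of its 74 calls, 2 were false. In the same simulation limma voom called 18% and 48%, and 2 of its 68 calls were false. DESeq2 ran on 12295 genes, called 23% and 70% of the same genes, and 29 of its 122 calls were false.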

Results

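Muscle gene expression was compared between the steer offspring of cows fed distillers grains during lactation and those of cows fed the control diet, 5 animals in each group. The question was whether the dam's diet while nursing was followed by a different muscle transcriptome in the grown offspring. Libraries of the DDGS group held 16942156 to 24936741 counts and those of the SBM group 17104353 to 19551577 counts. The counts were concentrated in few genes. The most abundant identifier, ENSBTAG00000043570, took 28.9% of all counts and the next, ENSBTAG00000026986, took 22.6%. Together they held 51.7% ± 1.5 of the counts in DDGS libraries and 51.2% ± 1.9 in SBM libraries (SD, n = 5 each). The 10 most abundant genes held 64.6% ± 1.8 and 64.2% ± 2.2. Neither share differed by more than the spread between animals (exact two-sided permutation p = 0.683 and 0.786, n = 5 each; adjusted p = 0.917 for both over 7 library measures). The median gene had only 38 to 72 counts.

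No gene passed the test between the groups. Of 12295 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05 or under 0.10, and the smallest adjusted p was 0.193. At an unadjusted p under 0.05 there were 460 genes, 175 with higher and 285 with lower fitted expression in DDGS. Evenly spread p-values would give 615, but other splits of the same 10 libraries gave a median of 391. Among 100 splits, the real one included, 33 gave at least 460. The lean to lower expression was seen in every alternative but 1, also without any single library. Without DDGS replicate 3 alone 186 were higher and 246 lower, and without SBM replicate 5 alone 157 and 227. The exception, chosen after the data had been seen, was the fit without both of these libraries. That fit gave 438 such genes, 223 higher and 215 lower. DESeq2 called 15 of the 14085 genes to which it gave an adjusted p, 2 higher and 13 lower in DDGS, and 7 of these 15 were among the 12295. With values of 1 set to 0 it called 4 genes, 0 higher and 4 lower in DDGS. On the 12295 genes limma voom called 0. The DDGS and SBM libraries did not overlap for 96 genes, where chance gives 0.794% of genes, or 97.6. The count in edgeR's quasi-likelihood test was 1 without DDGS replicate 4 and 0 without any other single library. The DESeq2 count was 3 without SBM replicate 5, 5 without SBM replicate 3, 25, 26 and 45 without SBM replicates 2, 4 and 1, and 218 without DDGS replicate 4.

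**Figure D1:**
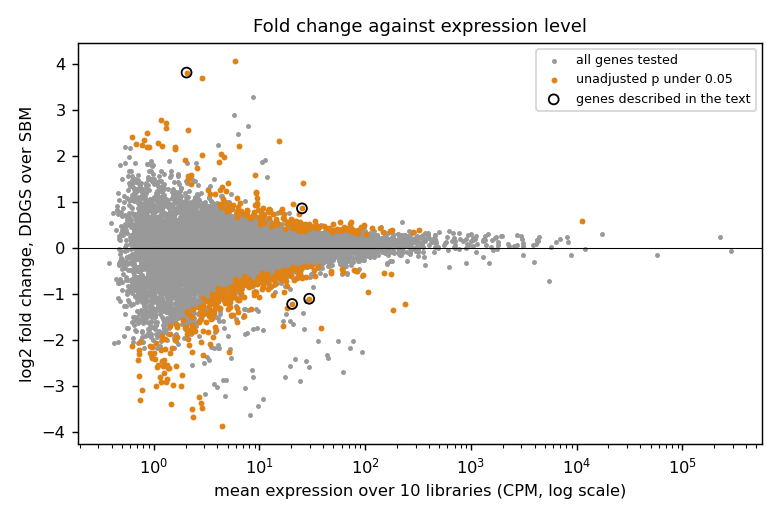
Log2 fold change, DDGS over SBM, against mean expression over the 10 libraries in CPM on a log axis; each point is 1 of the 12295 genes tested, orange points have an unadjusted p under 0.05 and open circles mark the 4 genes given by identifier. The scatter narrows with expression, and the 460 orange points include no gene with an adjusted p under 0.05.

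The size of a difference that these data leave open depended on expression. For 5667 genes, 46.1% of those tested, the unadjusted 95% interval of the fold change lay entirely within 2-fold in either direction, and for 2187 genes within 1.5-fold. Among the 2316 genes with a mean of 20 to 100 CPM, 94.9% had such an interval within 2-fold, and among the 449 genes above 100 CPM it was 94.2%. Their median standard errors were 0.19 and 0.17 on the log2 scale. Among the 4260 genes at 1 to 5 CPM only 2.56% had an interval within 2-fold, with a median standard error of 0.67, and none of the 819 genes below 1 CPM did. The direction of the genes at an unadjusted p under 0.05 also varied with expression. At 1 to 5 CPM 33 were higher and 123 lower in DDGS, and at 20 to 100 CPM 60 were higher and 29 lower. The median log2 fold change of all tested genes shifted the same way, from -0.148 at 1 to 5 CPM to 0.047 at 20 to 100 CPM. The direction is therefore not particular to the genes with a small p. The biological coefficient of variation, the square root of edgeR's dispersion, was 0.53 from the 1 common dispersion of all genes. From the median of the dispersions fitted as a trend on expression, it was 0.71 at 1 to 5 CPM and 0.28 at 20 to 100 CPM. With 1 library per animal, technical spread beyond counting is part of these values.

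The genes with the smallest p in each direction are given here by identifier, and none passed the adjusted threshold in edgeR's quasi-likelihood test. ENSBTAG00000014614 had 12.2 ± 2.4 CPM in DDGS and 28.5 ± 9.2 CPM in SBM libraries (SD, n = 5 each). Its log2 fold change was -1.22 with a standard error of 0.23 (edgeR adjusted p = 0.193), and the highest DDGS library, at 16.5 CPM, lay below the lowest SBM library, at 18.9 CPM. ENSBTAG00000007196 had 18.7 ± 3.0 CPM in DDGS and 40.4 ± 12.7 CPM in SBM libraries, a log2 fold change of -1.11 with a standard error of 0.21 (edgeR adjusted p = 0.193). Its groups did not overlap either, with 21.2 CPM as the highest DDGS and 27.5 CPM as the lowest SBM value. For both genes the exact two-sided permutation p of this single gene was 0.00794, the smallest that 5 against 5 can give. This p follows from the lack of overlap alone, which 96 genes showed where chance gives 97.6. DESeq2 called both, with adjusted p of 0.00467 for ENSBTAG00000014614 and 0.0056 for ENSBTAG00000007196. With values of 1 set to 0 the DESeq2 adjusted p was 0.0143 for both. Over the alternatives of all tools, most of them in edgeR, the adjusted p was 0.00467 to 0.998 for the first and 0.0056 to 0.999 for the second.

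In the other direction, ENSBTAG00000018253 had 32.6 ± 9.3 CPM in DDGS and 17.9 ± 4.8 CPM in SBM libraries (SD, n = 5 each), a log2 fold change of 0.86 with a standard error of 0.23 (edgeR adjusted p = 0.996). ENSBTAG00000034349 had 3.83 ± 4.80 CPM in DDGS and 0.262 ± 0.290 CPM in SBM libraries, a log2 fold change of 3.82 with a standard error of 0.96 (edgeR adjusted p = 0.996). Its counts were 6 to 235 in the DDGS libraries and 1 to 15 in the SBM libraries, of which 2 were listed at 1, so the size of its fold change is poorly determined: the log2 value was 2.69 without DDGS replicate 2 and 4.63 without SBM replicate 3. In DDGS replicate 2 it stood at 12.2 CPM, against 3.23 CPM in the next DDGS library. The exact two-sided permutation p was 0.0238 for ENSBTAG00000018253 and 0.0159 for ENSBTAG00000034349. DESeq2 called only the latter of this pair (adjusted p = 0.0102). With values of 1 set to 0 DESeq2 no longer called ENSBTAG00000034349 (adjusted p = 0.28). Over the alternatives of all tools that tested this gene the adjusted p was 0.0102 to 1.

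**Figure D2:**
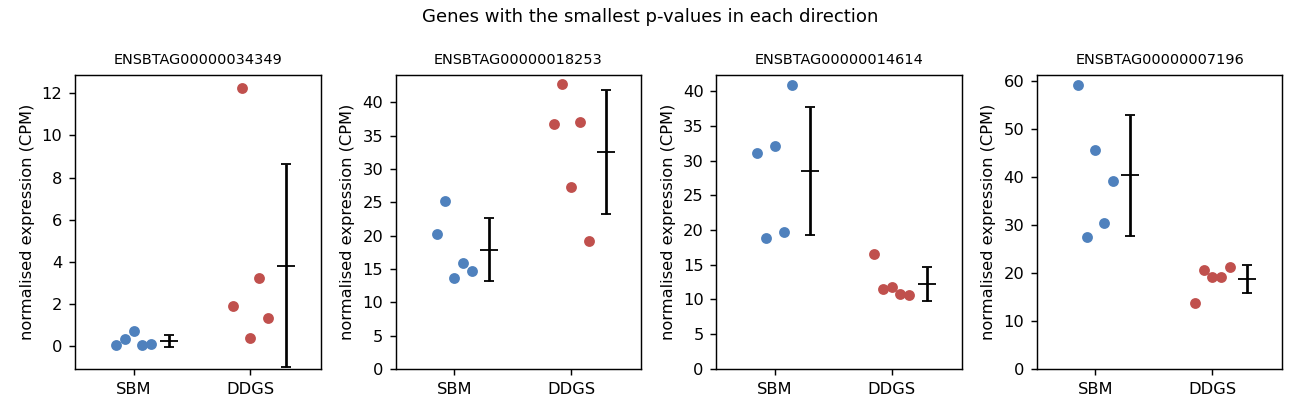
Normalised expression in CPM of the 4 genes with the smallest p in each direction; each point is 1 animal, and the bar beside each group is the mean with its SD (n = 5). For ENSBTAG00000014614 and ENSBTAG00000007196 every DDGS animal lies below every SBM animal, while for ENSBTAG00000034349 DDGS replicate 2, at 12.2 CPM, carries most of the DDGS mean.

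No separation of the libraries by maternal diet passed the test. Over the 500 most variable genes the median correlation distance was 0.773 between libraries of the same group and 0.944 between libraries of different groups. The difference of 0.171 did not exceed that of other splits of the animals by more than chance (exact one-sided permutation p = 0.111 over all splits). Among the fits without 1 library it reached p = 0.0397 (exact permutation) without DDGS replicate 4 and stayed above 0.05 without each of the others, with the smallest difference, 0.106, without SBM replicate 5. The difference was 0.0375 with a larger number of variable genes and 0.0628 without the largest of the sets of genes described next, to which 77 of the 500 genes belong. The first principal component held 41.5% of the variance of these genes, with mean positions of -15.2 ± 24.4 for DDGS and 15.2 ± 29.3 for SBM libraries (SD, n = 5 each; exact two-sided permutation p = 0.127, adjusted p = 0.875 over 7 measures). It ran from DDGS replicate 3, at -41.6, to SBM replicate 5, at 54.0. Without SBM replicate 1 the unadjusted p for this component was 0.0476 (exact permutation).

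**Figure D3:**
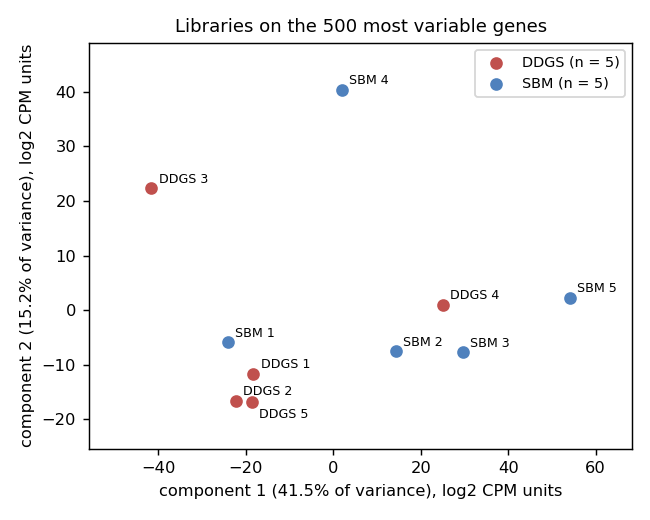
Positions of the 10 libraries on the first and second principal components of log2 CPM of the 500 most variable genes; each point is 1 animal, coloured by maternal diet. DDGS replicate 4 lies at 25.0 on the first component, among SBM replicates 2, 3 and 5, and SBM replicate 1 lies at -24.1, among DDGS libraries.

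Groups of genes varied together across animals, and for none of them did the difference between the diets pass an exact permutation test. Of 458 highly variable genes, 287 fell into 9 sets of at least 10 genes. The largest set held 149 genes, with a median pairwise correlation across libraries of 0.91. Its summed expression was 47 to 91 CPM in DDGS replicates 1, 2, 3 and 5 and 63 CPM in SBM replicate 1. In SBM replicates 2 and 4 it was 665 and 644 CPM, in DDGS replicate 4 it was 2187 CPM, in SBM replicate 3 it was 2696 CPM and in SBM replicate 5 it was 6547 CPM. Most genes of this set were listed at 1 in the libraries with the low sums, 133 of the 149 in DDGS replicate 3. All 88 of them in the main test had lower fitted expression in DDGS, and their smallest edgeR adjusted p was 0.996. Of the 88, 9 were at an unadjusted p under 0.05 in edgeR, against 460 of all 12295 genes tested. A common direction largely follows from grouping genes by their correlation across these same libraries, so the 88 are not separate observations. On the log2 scale the set averaged 7.08 in DDGS and 9.75 in SBM libraries, a difference of -2.67 (exact two-sided permutation p = 0.127, n = 5 each; adjusted p = 0.238 over 9 sets). A second set of 38 genes had 236 CPM in DDGS replicate 3 and 1683 to 5002 CPM in the other 9 libraries. A set of 12 genes had 466 CPM in DDGS replicate 2 and 3730 to 11584 CPM elsewhere, and a set of 13 genes, which includes ENSBTAG00000034349, had 452 CPM in DDGS replicate 2 and 19.6 to 134 CPM elsewhere. No set passed the test between the diets (smallest exact two-sided permutation p = 0.0952, adjusted p = 0.238, n = 5 each).

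**Figure D4:**
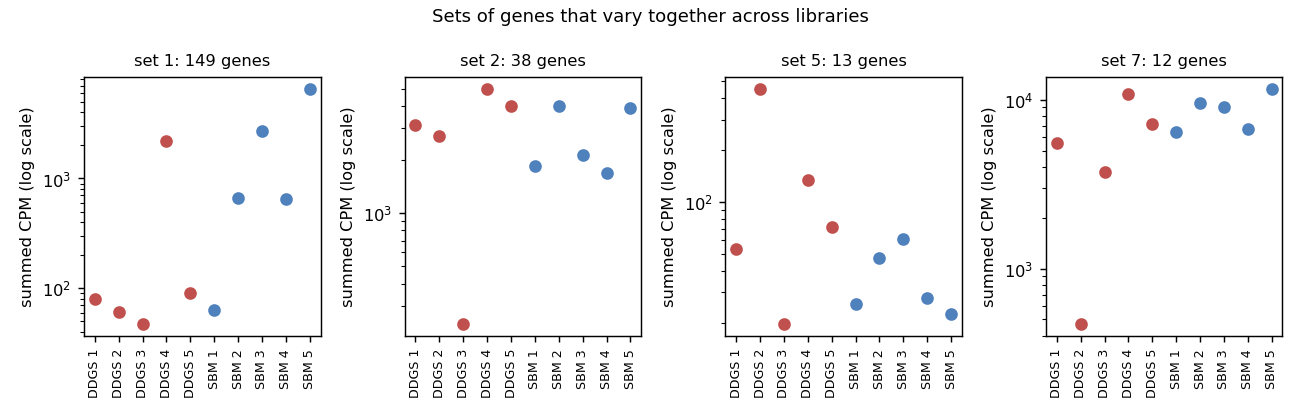
Summed CPM, on log axes, of 4 sets of genes that vary together, in each of the 10 libraries; each point is 1 animal, DDGS in red and SBM in blue. Set 1 with 149 genes is high in DDGS replicate 4 and SBM replicates 2 to 5, while sets 2 and 7 are low in DDGS replicates 3 and 2, respectively, and set 5 is high in DDGS replicate 2.

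Low counts were unusually distributed, and differently in each library. Between 2524 and 5078 of the 16963 genes were listed at 1 in a library, 3711 ± 791 in DDGS and 3672 ± 937 in SBM libraries (SD, n = 5 each; exact two-sided permutation p = 0.921). Above that value the number of genes per count value fell throughout the ranges examined only in SBM replicate 2, from 256 at 2 to 4 counts to 57.6 at 40 to 59 counts, and rose between some neighbouring ranges in the other 9 libraries, by more than 3 standard errors of counting in 3 of them, SBM replicates 3, 4 and 5. In SBM replicate 5 it was 49.0 per count value at 20 to 39 counts and 63.5 at 40 to 59 counts, a rise of 6.11 standard errors of counting. In SBM replicate 4 it rose from 56.0 at 5 to 9 counts to 72.9 at 10 to 19 counts. At mean counts of 100 to 300, the spread of a library around the others was 17.8 ± 4.6 times counting variance in DDGS and 24.1 ± 14.4 times in SBM libraries (exact two-sided permutation p = 0.468, n = 5 each), with 46.7 in SBM replicate 5.

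**Figure D5:**
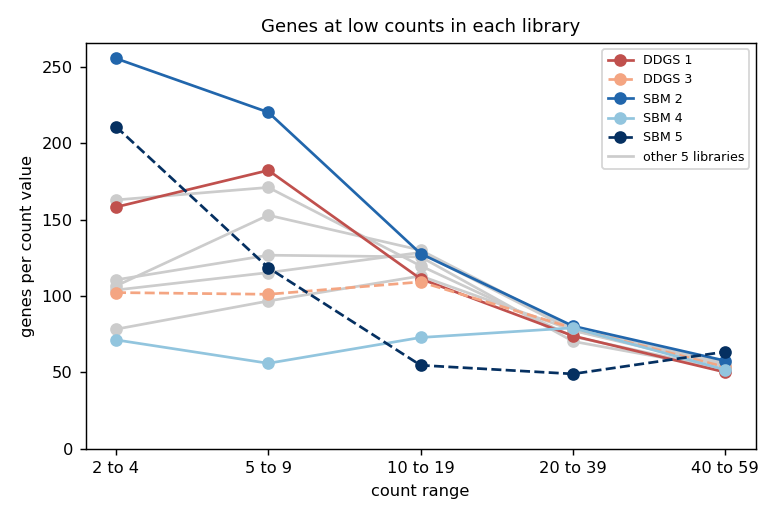
Number of genes per count value in 5 ranges of low counts, for each of the 10 libraries; lines join the values of 1 library. The curve of SBM replicate 2 falls throughout, while each of the other 9 rises between some neighbouring ranges, that of SBM replicate 5 from 49.0 to 63.5 between the last 2.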

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

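Apart from the splits of the libraries, the tests in this part were chosen only after the result or related values had been seen, namely those of amplified copies, a subtracted constant, a cutoff, sequencing depth, a common source, maternal diet for the largest set, single libraries and values of 1 for DESeq2. The values listed first are single animals far from the other 4 of their group by Dixon's criterion. Of 44 groups of 5 values examined, 9 held such an animal. Chance gives about 2.2 for independent, normally distributed values, but these values are linked and include sets and genes chosen for their variation or small p, so the excess is not evidence in itself. DDGS replicate 3 had 5078 genes listed at 1, against 3022 to 3528 in the other DDGS libraries, and a spread of 25.7 times counting variance against 13.9 to 16.9. SBM replicate 4 lay at 40.4 on the second principal component, against -7.73 to 2.29. DDGS replicate 2 had 12.2 CPM of ENSBTAG00000034349 and 452 CPM of the set of 13 genes that includes it, against at most 3.23 and 134 CPM. DDGS replicate 1 had the highest DDGS value of ENSBTAG00000014614, 16.5 CPM, and the lowest of ENSBTAG00000007196, 13.7 CPM. DDGS replicate 4 had 2187 CPM of the largest set, against 46.8 to 91.2 CPM in the other DDGS libraries, and 68.9 CPM of a set of 10 genes, against 6.72 to 22.1 CPM.

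The largest set, 149 genes that were near the floor of the table in some animals and reached 6547 CPM in another, is the pattern most worth following up. Sequencing depth does not account for it: the set was 140 times higher in SBM replicate 5 than in DDGS replicate 3, whose totals differed by a factor of 0.982. RNA of a tissue other than muscle, in amounts that differ between samples, may be the source, but the members' ratios to SBM replicate 5 varied to different degrees, with standard deviations on the log2 scale of 0.55 in SBM replicate 3, 0.82 in DDGS replicate 4, 1.1 in SBM replicate 2 and 3.06 in SBM replicate 4. Of the genes expected at 50 counts or more, 0 of 72 in DDGS replicate 4, 0 of 72 in SBM replicate 3, 0 of 49 in SBM replicate 2, 2 of 4 in DDGS replicate 1 and 8 of 32 in SBM replicate 4 were listed at 1, where a single source was to give fewer than 1 in 100 and 5 or more in a library was to count against it; a minimum of 150 counts, tried only after that result was seen, gave 3 of 13 in SBM replicate 4 and 0 elsewhere. The mark of 5 or more, set to count against a single source, was thus reached in SBM replicate 4, with 8 of 32. It was reached in that library alone, whose spread was 28.8 times counting variance, and DDGS replicate 1 had only 4 such genes. Because the result rests on 1 library, a single source was not taken as excluded. Several sources and maternal diet stay open too, the latter with an exact permutation p of 0.127 in 5 against 5 animals. Without gene names no tissue can be proposed.

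The deficit of low counts and the wide spread between libraries might be explained by reads that are amplified copies of few molecules. Libraries with more genes listed at 1 had the wider spread over counting variance (Spearman rho = 0.891, permutation p = 0.00129; Pearson r = 0.563, permutation p = 0.0859; 10 libraries, 1 relation tested). Pearson's r was 0.556 without DDGS replicate 3 and SBM replicate 4, the libraries farthest from the median number of genes listed at 1, and 0.937 without SBM replicate 5, the library farthest from the median spread. A cutoff above 4 counts, below which values became 1, is argued against by the 214 or more genes at 2 to 4 counts in every library, while subtraction of a constant stays open, since it would keep the shape of the counts and the rise of 6.11 counting errors in SBM replicate 5 does not go against it. Differences between animals add to the spread and cannot be separated from it with 1 library per animal.

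DESeq2 called 15 of 14085 genes with an adjusted p, where edgeR's quasi-likelihood test called 0 of 12295, and 7 of the 15 were among the genes that edgeR tested. Chance cannot be excluded: 8 of 40 splits of the libraries, the real one included, gave at least 15 DESeq2 calls, and the highest other split gave 188. Many of the calls depended on SBM replicates 5 and 3: 2 of the 15 stayed without the former and 4 without the latter. Without any other single library 8 to 15 stayed. Of the 15, 7 belonged to sets of genes varying together, ENSBTAG00000034349 to that of 13 genes and the others to 1 of 16 genes. The set of 16 stood at 56.7 and 153 CPM in SBM replicates 3 and 5 and at 2.09 to 6.25 CPM elsewhere. Its calls are thus not separate observations. Without DDGS replicate 4, 218 genes were called, 122 of them from the largest set. Whether the 15 calls reflect the listing at 1 stays open. Of the 15, 7 were at 1 in all DDGS libraries, and 4 stayed when values of 1 were set to 0. The 11 others ended through larger errors. Their median absolute log2 fold change was 5.15 before and 7.52 after, and their median standard error 1.2 and 3.03. Genes with an adjusted p rose from 14085 to 16476. No biological explanation was tested for these calls.

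For edgeR's quasi-likelihood test, 33 of 100 splits gave at least the 460 genes at an unadjusted p under 0.05 of the real split. The other splits had a median of 391 such genes and a highest value of 1152, so chance cannot be excluded for that count. The 0 calls of the real split cannot be tested in this way, because any split gives at least 0 (100 of 100). The highest other count of calls, picked after it was seen, was 58; of the splits other than the real one, 7 made any call, this one included, and the median was 0. It came from the split that set DDGS replicates 1, 2, 3 and 5 with SBM replicate 1 against the rest. It differs from the real split by the exchange of DDGS replicate 4 and SBM replicate 1, and its first 5 libraries are those with 46.8 to 91.2 CPM of the largest set, against 644 to 6547 CPM in the rest. Such a count may point to a structure of the samples, which was not tested, nor was whether the 58 genes belong to the set.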

How the results depend on the processing

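The count of 0 genes in edgeR's quasi-likelihood test was also found in 25 of 28 alternatives. Of all 28, 22 were fixed before the data were examined. The exceptions were 15 genes with DESeq2, 4 genes with DESeq2 after values of 1 had been set to 0, and 1 gene, lower in DDGS, without DDGS replicate 4. The first and the last of these exceptions were among the 22. Leaving out each library in turn gave 0 to 1 genes. The alternatives chosen after seeing the data were values of 1 set to 0 in either tool, the removal of DDGS replicate 3 with SBM replicate 5, the removal of the largest set, its level as a covariate, a minimum of 10 CPM in 5 libraries, and, for the separation and the library measures, leaving out single libraries or the largest set. Genes at an unadjusted p under 0.05 numbered 180 with that minimum and 1355 without any filter, against 460, and the number of genes tested differs between these. With the replicate number as a block 0 genes passed. Expression showed no strong pairing by number: same-numbered libraries deviated together with correlations of -0.07 to 0.07, and 0 of 5 pairs were each other's best match. For DDGS replicates 1 and 5 the same-numbered SBM library was the best match, but not the reverse. Whether a number marks a shared sire, day or batch cannot be told from these values. The 4 genes given by identifier kept their direction in every alternative that tested them. Their only calls were in DESeq2: ENSBTAG00000034349, ENSBTAG00000014614 and ENSBTAG00000007196 as deposited, and the last 2 also with values of 1 set to 0. The separation of the libraries was 0.106 to 0.222 when 1 library was left out, with exact one-sided permutation p of 0.0397 (without DDGS replicate 4) to 0.23, and it was 0.0375 with a larger number of variable genes (p of 0.214), 0.166 with RLE factors (0.127) and 0.0628 without the largest set (0.119). Of 70 values of library measures with 1 library left out, 69 stayed on their side of 0.05. The alternatives for gene lists and list scores, fixed beforehand, were not run, because no identifier could be matched to a symbol. Low expression went with fewer calls: in simulated data, in which depth was not varied, edgeR called 34.8% of 46 changed genes at 2-fold and 83.3% of 54 at 4-fold in the more highly expressed part, against 17% and 55% overall. Most 2-fold changes were thus missed in that part too.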

Other observations

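All of the sets and the gene described in this part were examined only after the data had been seen. Beyond the sets already described, 5 smaller sets of 10 to 27 genes varied together, and 3 of them were lowest in DDGS replicate 3 and highest in SBM replicate 5. A set of 27 genes had 21.3 CPM in DDGS replicate 3, 37.5 CPM in SBM replicate 4 and 501 CPM in SBM replicate 5. A set of 12 genes had 5.45 CPM in DDGS replicate 3 and 41.4 to 299 CPM in the others, and a set of 10 genes had 1.38 CPM there and 12.9 to 104 CPM in the others. A set of 16 genes was at 2.09 to 6.25 CPM in 8 libraries, at 56.7 CPM in SBM replicate 3 and at 153 CPM in SBM replicate 5. Of the 15 genes that DESeq2 called, 7 belonged to one of the 9 sets and 0 to the largest. Among these 7, ENSBTAG00000034349 belonged to the set of 13 genes described above and the others to the set of 16 genes.

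Within the largest set, ENSBTAG00000046089, singled out after its values were seen because it had the highest count, was listed at 1 in DDGS replicates 1, 2 and 3 and SBM replicate 1 and at 14 counts in DDGS replicate 5. It reached 1004 counts in SBM replicate 2, 1675 in SBM replicate 4, 2956 in SBM replicate 3, 3050 in DDGS replicate 4 and 9174 in SBM replicate 5. The largest set made up 0.655% of the counts of SBM replicate 5. A stricter distance limit of 0.1 left 82 genes in it, all members of the 149, and a limit of 0.3 gave 194 genes that include all 149.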
